A study of Mus musculus with 8 samples.

How the data were processed

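Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in granule cell progenitors sorted by Atoh1-GFP fluorescence from mouse cerebella on postnatal day 1. Per the labels, 6 libraries came from 100, 500 or 1000 cells with a low-input protocol, and 2 libraries came from 20000 cells with standard ATAC-seq. Each cell number had 2 replicates. The labels do not say whether replicates came from separate animals or sorts, so p-values measure the spread between these libraries, which may be technical. The labels also do not say how the Atoh1-GFP reporter was built, and a transgene that carries Atoh1 flanking sequence would add reads over that sequence.

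Each library had its own deposited peak list, so peaks were called per library and replicates were not pooled. Bowtie2, MACS2 and the mouse build mm10 are named in the submitters' processing notes, without versions or settings. The deposited score of a peak equalled 10 times its −log10 p, cut to a whole number, and was not used further. The deposited fold is the authors' enrichment of the peak summit over the background of the same library. The authors' −log10 p and −log10 q values refer to that summit in that library alone. The deposited summit offset counts base pairs from the peak start. The smallest deposited −log10 p was 2.00 and the shortest peak was 150 bp in every list. Peak names were numbered by p in the deposited lists. The 6 low-input lists held autosomes 1 to 19 only and lacked between 1.80% and 2.00% of the peak numbers, so peaks had been taken out after calling. The 20000-cell lists had no gaps and included chromosome X, chromosome Y and unplaced sequences. The lists were thus filtered differently, and autosome values are printed beside values over all chromosomes for most results.

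Several deposited peaks could mark summits of 1 accessible region, so overlapping or touching peaks were merged into regions, which kept the highest fold and −log10 p of their peaks. Fold values set the classes by fold and the named regions and genes of highest fold, and are printed side by side only as the authors' values. Percentiles within a library, and lists cut to the strongest regions of each library, followed −log10 p instead. A region with a lower fold can therefore stand at a higher percentile. The fold has the form (k + 1)/(λ + 1), with k the reads at the summit and λ the background, and both were recovered from the deposited fold and −log10 p by inverting the Poisson tail, within 0.001. This succeeded for at least 99.6% of peaks in each library. The genome background of each library, in reads expected at a summit, served as its relative depth. Total read numbers were not used here. The added 1 in the fold compresses values in shallow libraries.

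Genes came from a RefSeq table of the same assembly, with gene starts and ends but no strand, exons or transcripts. The planned promoter could therefore not be set at transcription start sites, and a region within 1 kb of either annotated end of a protein-coding gene was counted in its place, called a gene-end region, which includes 3′ ends. The planned count of sequence motifs at summits was not run, because no genome sequence was used here.

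Recovery was the share of the regions of a 20000-cell library overlapped by at least 1 bp by a low-input library, averaged over both 20000-cell libraries. Chance recovery came from 10 shifts of the regions along their chromosomes in steps of 100 kb. Regions called in both 20000-cell libraries formed a consensus. Trends used Pearson's r and Spearman's rho with log10 cell number and exact two-sided permutation of all pairings, with Benjamini-Hochberg adjustment over 5 trends. Concordance was the base-pair Jaccard index, shared length over total covered length, and its mean within groups was ranked among all ways of pairing 8 libraries, exact and one-sided. Recovery at gene ends and away from them was compared within 10 classes of equal size by fold, and its sign was tested over 6 libraries by an exact sign-flip test. Gene lists were compared by Fisher's exact test, which treats genes as units and describes these libraries. An exact permutation of 2 libraries against 2 others cannot reach a p below 0.333, so differing genes were counted, with the same count for the other splits of those 4 libraries.

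The named genes followed a rule set before the data were examined. It took the Atoh1 locus and 9 other granule genes. From each list it took members whose state differed between 100 and 20000 cells, with up to 4 further members in alphabetical order. It also took the 10 consensus 20000-cell regions with the highest mean fold. Last came the 10 strongest regions and 5 strongest genes of the 100-cell or 20000-cell group that were missing from the other. Some genes that the rule selected are not reported here. The 15 gene lists were fixed at the same time. Alternatives were deposited peaks with −log10 q of at least 5, lists cut to the 105388 strongest regions of each library (the length of the shortest list), windows of 500 bp and 2 kb, other overlap rules, a replicate block and leaving out each library. Lists of the 50000 strongest regions, and autosomes only for results on gene ends, were added after seeing the data.

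Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. Summit reads came back exactly in 100% of 18947 simulated summits. A list simulated from the 122758 regions of 20000-cell replicate 1 with a built-in recovery of 69.9% gave 70.4%. Overlaps and Jaccard values on chromosome 1 equalled those of bedtools 2.31.1.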

Results

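The series asked how few cells suffice for a map of open chromatin, using granule cell progenitors, the dividing precursors of cerebellar granule neurons, as test material. There were 8 libraries, 2 each from 100, 500, 1000 and 20000 sorted cells. Standard ATAC-seq was used only at 20000 cells, so cell number and protocol changed together there. The background at a summit, a measure of relative depth, was 1.03 ± 0.235 reads at 100 cells, 2.43 ± 0.301 at 500 cells, 2.33 ± 0.204 at 1000 cells and 5.37 ± 0.211 at 20000 cells (SD, n = 2 each). Depth thus rose with cell number as well, with r = 0.957 between their log10 values (exact p = 0.00397, n = 8; Spearman's rho = 0.829, exact p = 0.0198; r = 0.908 and exact p = 0.0556 without the 20000-cell pair).

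Open chromatin around Atoh1, the transcription factor gene that marks granule progenitors, was called in all 8 libraries. Atoh1 lies on chromosome 6 (64729125 to 64731245, mm10). The strongest region of the locus (64733355 to 64735080) began 2109 bp beyond the higher-coordinate end of the gene. By −log10 p it ranked at a mean percentile of 99.7 or higher within its own library's list at every cell number. The authors' fold there was 8.49 ± 0.119 at 100 cells, 6.51 ± 0.633 at 500 cells, 6.96 ± 0.758 at 1000 cells and 9.96 ± 0.0026 at 20000 cells (SD, n = 2 each). A pair of further regions, at 64727572 to 64728375 and over the lower-coordinate gene end at 64728570 to 64729626, were also called in all 8 libraries.

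**Figure D1:**
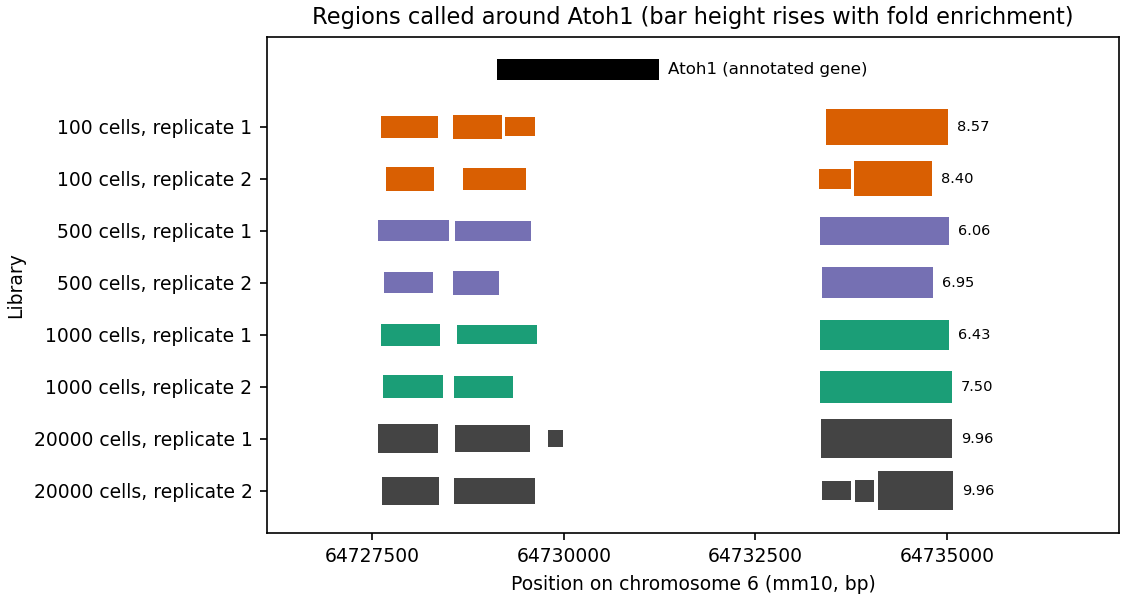
Regions called around Atoh1 in each of the 8 libraries, by position on chromosome 6 in bp (mm10), with bar height rising with the authors' fold and the fold printed for the strongest region. The strongest region lay beyond the gene and had folds from 6.06 to 9.96.

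Other genes of the lineage had gene-end regions at each cell number. The region at Zic1 and Zic4, zinc finger genes of granule progenitors (chromosome 9, 91365638 to 91366116), stood at mean percentiles of 92.1, 77.7, 74.9 and 93.9 of the lists from 100, 500, 1000 and 20000 cells. Neurod1, a transcription factor gene of granule neuron differentiation, had a region on chromosome 2 (79456396 to 79457103) at percentiles of 89.6, 85.6, 89.7 and 93.1. The region of Pax6 (chromosome 2, 105668207 to 105668965) stood at 84.6, 84.1, 82.2 and 88.0, and that of Barhl1 (chromosome 2, 28908234 to 28909018) at 61.1, 73.4, 77.4 and 73.8. Among genes of the Sonic hedgehog pathway, which drives progenitor division, Gli1 (chromosome 10, 127341615 to 127342741) stood at 89.4, 84.6, 92.5 and 70.6, and Ptch1 (chromosome 13, 63573343 to 63574034) at 56.4, 59.4, 71.3 and 58.3. Mycn (chromosome 12, 12942214 to 12942989) stood at 84.1, 90.5, 89.3 and 86.3, and Ccnd2 (chromosome 6, 127150925 to 127151268) at 69.5, 42.6, 65.2 and 65.2. The strongest gene-end region of Ccnd1, a cyclin gene (chromosome 7, 144939525 to 144939946), was called in 7 of 8 libraries, and counts by gene accept any region at either gene end. Percentiles come from lists of different lengths and depths, so they cannot show a change between cell numbers. Replicates could also differ widely, as for Ptch1 at 100 cells (26.9 and 85.8).

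Gene lists of the granule lineage were nearly complete at 100 cells. All 19 Sonic hedgehog genes, including Bmi1, Boc, Ccnd1 and Ccnd2, and all 20 cell cycle genes, including Aurka, Aurkb, Bub1 and Ccna2, had a gene-end region in both libraries of every group. Of 22 progenitor identity genes, 20 did at 100 cells, 21 at 500 and at 1000 cells, and 22 at 20000 cells. Among members that differed between 100 and 20000 cells, Id3 was missing in 100-cell replicate 2 only. Atoh1, Barhl1, Barhl2 and Id1 were present throughout. Of 24 genes of differentiating granule neurons, 20 had such regions at each low input and 22 at 20000 cells, with Dcx (chromosome X) and Nfia the differing members. Astn1, Cbln1, Cbln3 and Chn2 were present throughout, while Gabra6, a receptor subunit gene of mature granule neurons, was called in 1 library and Rbfox3 in 3.

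Markers of other cell types were less often open at their gene ends. The progenitor identity, Sonic hedgehog and differentiating neuron lists were pooled, without Meis2, which the unipolar brush and nuclear neuron list also holds. Of these 64 genes, 90.6% had a region in both libraries at 100 cells, against 52.0% of 125 genes of other cell types (odds ratio 8.92, Fisher's exact test, Benjamini-Hochberg p = 6.53e-08). By the same exact test the odds ratio was 11.2 at 500 cells (p = 1.2e-08), 9.27 at 1000 cells (p = 1.47e-07) and 23.6 at 20000 cells (p = 3.02e-09). On autosomes it was 12.7, 17.8, 14.6 and 22.3. The difference between groups in these ratios was not tested.

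The lists of other cell types differed among themselves. Microglia and macrophage genes had regions in both libraries in 4, 4, 4 and 3 of 13 genes from 100 to 20000 cells. Set against all other autosomal genes in each group, this list was below them in all 4 groups (Fisher's exact test, Benjamini-Hochberg p from 0.0102 to 0.0458 over 60 tests). The erythroid list, with 2 of 9 autosomal genes in each group and none of its 2 genes on chromosome X, was also below (exact test, p from 0.0357 to 0.0378). Purkinje cell genes reached 12, 11, 12 and 12 of 13 and unipolar brush and nuclear neuron genes 9, 9, 8 and 9 of 10, and neither list passed the adjusted test in any group. By the same exact test the differentiating granule neuron list did not pass at 100, 500 or 1000 cells (20 of 23 autosomal genes, adjusted p = 0.0581 each) and did at 20000 cells (21 of 23, adjusted p = 0.0258). The progenitor identity, Sonic hedgehog and cell cycle lists were above other genes in all 4 groups (exact test, adjusted p from 0.00215 to 0.00904), and housekeeping genes at 500, 1000 and 20000 cells (exact test, adjusted p from 0.00318 to 0.0208). GABAergic interneuron genes had 7, 8, 8 and 9 of 13, astrocyte and Bergmann glia genes 8, 7, 10 and 8 of 13, oligodendrocyte genes 6, 6, 6 and 8 of 13, and endothelial and mural genes 5, 5, 7 and 7 of 13. Hair cell genes had 8, 8, 9 and 9 of 13, and liver and muscle genes 5 of 14 in each group. Between 100 and 20000 cells the differing members included Gad2 and Slc32a1 (GABAergic), Pdgfra (oligodendrocyte), Tek and Acta2 (endothelial and mural) and Gfi1 (hair cell), called in both libraries at 20000 cells and not in both at 100 cells, and C1qc (microglia), called in both libraries at 100 cells and in neither at 20000 cells. Housekeeping genes had 16, 17, 18 and 20 of 20, with Hprt and Pgk1 on chromosome X, Actb missing in 100-cell replicate 1 and Ywhaz called in 5 libraries. An open gene end does not measure expression.

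**Figure D2:**
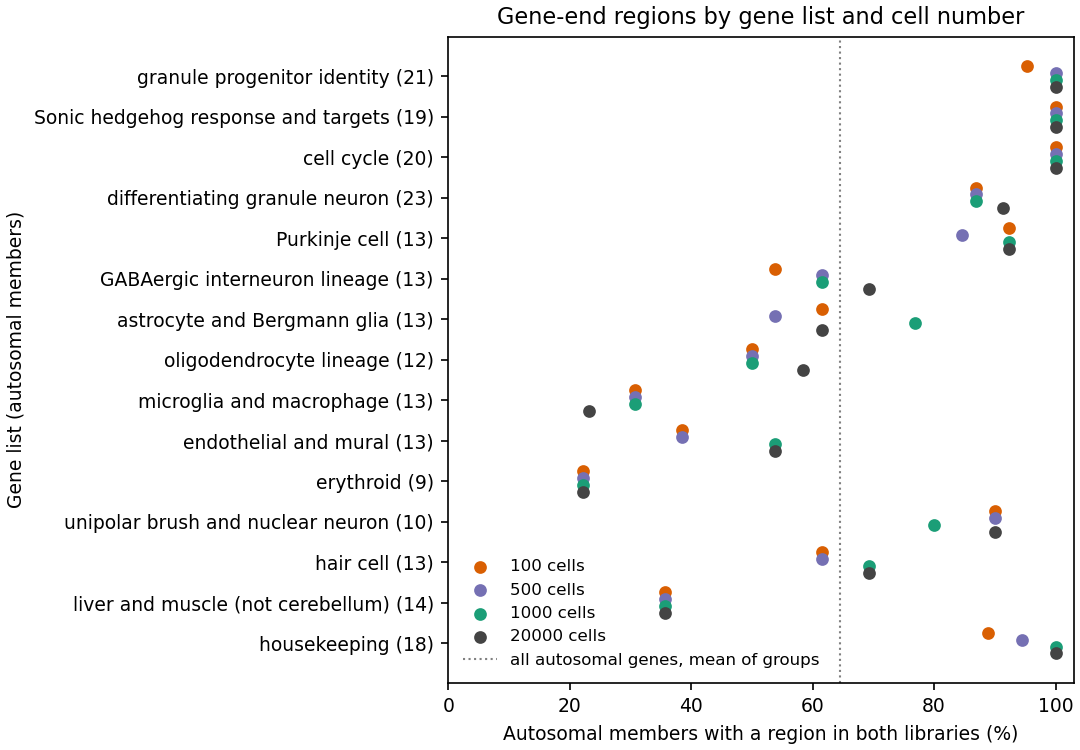
Percent of autosomal members of each of 15 gene lists with a gene-end region in both libraries of a group, with 1 point per cell number and the number of autosomal members in parentheses; the dotted line is the mean over groups for all autosomal genes. Sonic hedgehog and cell cycle genes lie at 100% in all 4 groups, and erythroid genes at 22.2%.

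The number of accessible regions showed no trend with cell number that passed the test. Regions were wider and covered more sequence in the 20000-cell than in the 100-cell group, but these trends did not pass after adjustment. There were 123412 ± 22452 regions at 100 cells, 112376 ± 4033 at 500 cells, 110873 ± 7757 at 1000 cells and 124927 ± 3067 at 20000 cells (SD, n = 2 each). The median region was 239.5 ± 7.78 bp wide at 100 cells, 262 ± 22.6 at 500 cells, 309.5 ± 20.5 at 1000 cells and 310.5 ± 2.12 bp at 20000 cells. Covered length was 43.9 ± 7.01, 44.0 ± 2.02, 49.2 ± 0.820 and 54.6 ± 1.07 Mb. Region number gave r = 0.149 with log10 cell number (exact p = 0.738, adjusted 0.738, n = 8; rho = 0.195, exact p = 0.672; r = −0.485, exact p = 0.333 over the 6 low-input libraries). On autosomes the 20000-cell group had 122402 regions over 53.4 Mb, and region number gave r = 0.0585 (exact p = 0.891, n = 8). Covered length gave r = 0.813 (exact p = 0.0155, adjusted 0.0575, n = 8; rho = 0.781, exact p = 0.0349), and r = 0.481 (exact p = 0.344) at low input alone. Width gave r = 0.786 (exact p = 0.0230, adjusted 0.0575, n = 8; rho = 0.878, exact p = 0.0103) and r = 0.832 (exact p = 0.0444) at low input alone. The result on region number depended on the peak threshold and on 100-cell replicate 2, which had 139288 regions. Without merging, peaks numbered 160059, 161734, 174538 and 188207 at 100, 500, 1000 and 20000 cells (r = 0.704, exact p = 0.0516, n = 8). With −log10 q of at least 5 the numbers were 40543, 40542, 50492 and 72173 (r = 0.937, exact p = 0.00437, n = 8; r = 0.629, exact p = 0.222 over the 6 low-input libraries), and without that replicate r was 0.847 (exact p = 0.0206, n = 7).

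Low-input libraries found most strong regions of the standard map and fewer weak ones. Of the regions of a 20000-cell library, 56.7% ± 4.51 were overlapped at 100 cells, 56.6% ± 2.79 at 500 cells and 61.8% ± 1.01 at 1000 cells (SD, n = 2 each). The 20000-cell libraries overlapped each other by 75.3% ± 1.93, and shifted regions gave from 4.36% to 4.75% per group. On autosomes recovery was 57.9%, 57.7% and 63.1%. In the strongest of 10 classes by fold of the autosomal consensus, 99.1% ± 0.334, 99.2% ± 0.155 and 99.6% ± 0.0489 were recovered at 100, 500 and 1000 cells, and in the weakest class 39.2% ± 5.74, 39.6% ± 4.78 and 45.9% ± 0.375. The consensus holds only regions called in both 20000-cell libraries. It therefore cannot show how many weak regions another 20000-cell library would miss.

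**Figure D3:**
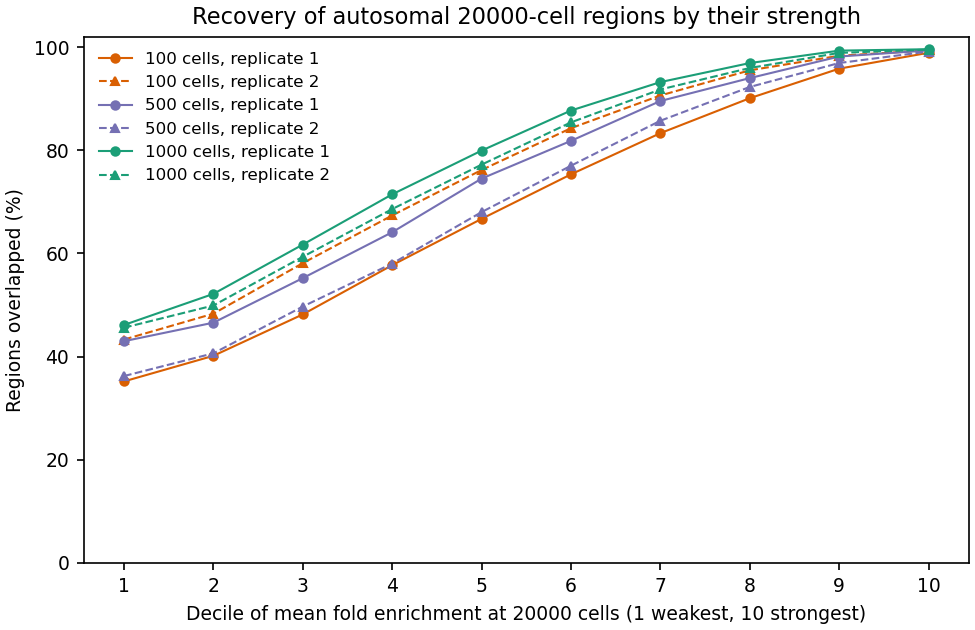
Percent of autosomal regions called in both 20000-cell libraries that each of 6 low-input libraries overlapped, by decile of mean fold at 20000 cells from weakest (1) to strongest (10). Group means rise from between 39.2% and 45.9% in the weakest decile to at least 99.1% in the strongest.

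Of 86723 autosomal consensus regions, 52.8% were called in all 6 low-input libraries and 7.58% in none. The trend of recovery with cell number did not pass the test (r = 0.530, exact p = 0.267, adjusted 0.333, n = 6; rho = 0.717, exact p = 0.178). Without the 100-cell pair r was 0.872 (exact p = 0.333, n = 4), and recovery gave r = 0.431 with the background (exact p = 0.386, n = 6; rho = 0.257, exact p = 0.658; r = 0.0513 and exact p = 1.00 without the 100-cell pair, whose background was farthest from the median).

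Some of the strongest 20000-cell regions were absent from every low-input list. Of the 10 with the highest mean fold, 7 were in no low-input list, led by a region 35186 bp from Pak3 on chromosome X (143482934 to 143483179, fold 46.0 ± 0.785) and one within Chl1 on chromosome 6 (103648991 to 103649357, fold 33.9 ± 1.12). The 3 called in all 8 libraries overlapped Pnp (chromosome 14, 50944198 to 50944925, fold 26.4 ± 0.217 at 20000 cells), Zfp960 (chromosome 17, 17063587 to 17064346, fold 26.4 ± 1.78) and Gm14410 (chromosome 2, 177205914 to 177206838, fold 26.1 ± 0.3995). The 10 strongest consensus regions missing at 100 cells were all in no low-input list, and included regions within Cmss1 and Filip1l and within Cdk8. Others had Pex2, Dpy19l2, Rpusd4 and Axin2 as the nearest genes, at 281690, 14815, 29193 and 60792 bp. The low-input and 20000-cell lists had been filtered differently, so absence at this rank does not measure loss at low input. In a selection made after seeing the data, the strongest missing at 100 cells but called in another low-input library lay on chromosome 6 (9718755 to 9719662, fold 15.2 ± 0.524), 469135 bp from Nxph1.

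Of 88679 consensus regions of the 20000-cell libraries, 17012 were in neither 100-cell library, and on autosomes 15056 of 86723. The reverse selection, regions of both 100-cell libraries absent at 20000 cells, held 3754 of 62434 regions (6.01%). The strongest lay near Krt84 on chromosome 15 (101519863 to 101520305, fold 10.5 ± 0.913 at 100 cells), within Ulk4 on chromosome 9 (121240020 to 121240723, fold 9.83 ± 5.54) and within Vps53 on chromosome 11 (76167231 to 76167715, fold 9.16 ± 0.658). Others lay 3191, 12702 and 3223 bp from Jph2, Spesp1 and Fam220a and within Anapc5, Slfn5, Iqgap1 and Ece1. Each of these 10 was called in all 6 low-input libraries.

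Overlap was higher on average within than between cell numbers, which rested on the 20000-cell pair. The Jaccard index within pairs was 0.426 at 100 cells, 0.471 at 500 cells, 0.545 at 1000 cells and 0.632 at 20000 cells. The 100-cell pair lay below the pairings of its replicate 1 with the 500-cell and 1000-cell libraries (0.440 to 0.481), and the 500-cell pair below those of its replicate 1 with the 1000-cell libraries (0.519 and 0.535). The mean Jaccard index was 0.519 within groups and 0.472 between groups (exact one-sided p = 0.0190 among all pairings of the libraries, n = 8). Among the 6 low-input libraries it was 0.481 and 0.474 (exact p = 0.133 among 15 pairings, where the smallest possible p is 0.0667). Without 20000-cell replicate 1 or 2 the excess was 0.00940 (exact p = 0.238, n = 7) or 0.00659 (exact p = 0.352, n = 7). Leaving out 500-cell replicate 2 or either 1000-cell library also ended the call (exact p from 0.0667 to 0.133, n = 7), although the excess was 0.0545 without the former and 0.0429 or 0.0467 without 1000-cell replicate 1 or 2, against 0.0464 with all libraries.

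**Figure D4:**
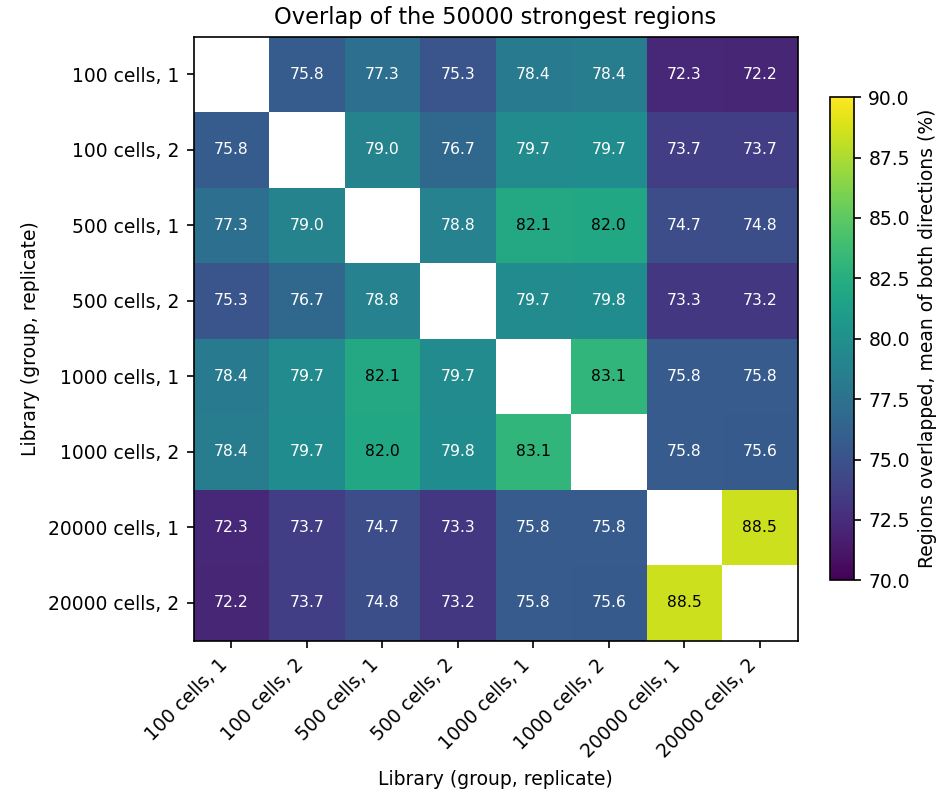
Overlap of the 50000 strongest regions by −log10 p between each pair of 8 libraries, in percent, as the mean of both directions. The 20000-cell pair stands at 88.5%, pairs of low-input libraries at 75.3% to 83.1%, and mixed pairs at 72.2% to 75.8%.

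The share of regions at gene ends showed no trend with cell number that passed the test in the whole lists. It was 16.2% ± 2.70 of regions at 100 cells, 16.6% ± 0.393 at 500 cells, 16.5% ± 0.857 at 1000 cells and 14.5% ± 0.378 at 20000 cells (SD, n = 2 each). On autosomes the share at 20000 cells was 14.3%, and regions outside genes were 39.8%, 39.8%, 39.6% and 44.0% of autosomal regions. The trend had r = −0.518 (exact p = 0.195, adjusted 0.325, n = 8; rho = −0.439, exact p = 0.300; r = 0.127, exact p = 0.811 over the 6 low-input libraries). It passed in lists of equal length, where the shares were 17.7%, 17.2%, 17.0% and 15.97% (r = −0.893, exact p = 0.00476, n = 8), but not within the low-input libraries alone (r = −0.616, exact p = 0.144, n = 6). Peaks with −log10 q of at least 5 gave r = −0.915 (exact p = 0.00397, n = 8), but r = −0.625 (exact p = 0.189, n = 6) at low input alone, and leaving out 100-cell replicate 2 gave r = −0.939 (exact p = 0.00476, n = 7).

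At matched fold, gene-end regions were found at low input more often than regions away from gene ends. The difference in recovery was 16.9 ± 3.43 percentage points at 100 cells, 16.8 ± 0.775 at 500 cells and 14.3 ± 1.15 at 1000 cells (SD, n = 2 each). Its mean was 16.03 points, above 0 in 6 of 6 libraries (exact sign-flip p = 0.0312, the smallest possible with n = 6), and 17.2 points on autosomes. Without matching, the mean difference over all chromosomes was 21.7 points. On the autosomal consensus, unmatched gene-end regions were recovered at 93.2%, 93.1% and 95.1% and others at 68.4%, 68.2% and 74.5%.

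Nearly all genes open at their ends at 20000 cells were also open at low input. Of 20665 autosomal protein-coding genes, 13278, 13230, 13440 and 13419 had a gene-end region in both libraries at 100, 500, 1000 and 20000 cells. Of those at 20000 cells, 96.0%, 95.9% and 97.1% were also found in both libraries at 100, 500 and 1000 cells. Between 100 and 20000 cells, 611 genes had a region in both libraries at 20000 cells and in neither at 100 cells, of which 454 lay on chromosome X and 152 on autosomes. In the opposite direction there were 181 genes, all autosomal. The other splits of these 4 libraries gave 86 and 36, and 64 and 44. With 2 against 2 libraries an exact permutation test cannot pass 0.05, and no other test was run. With −log10 q of at least 5 the 611 and 181 became 993 and 61. The 181 became 620 without 100-cell replicate 1, 392 without 100-cell replicate 2, and 275 or 296 without 20000-cell replicate 1 or 2.

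Of the 152 autosomal genes missing at 100 cells, 96 were called in another low-input library. The highest folds among the 611 belonged to Rtl8b, Enox2, Haus7 and Fam3a on chromosome X and Ddx3y on chromosome Y, which the low-input lists do not cover. The highest autosomal folds, a selection made after seeing the data, were at Bbs2 (mean fold 15.8), Trmt11 (14.8), Hjurp (14.2), Cwc22 (13.4) and Crebzf, in falling order. Of these only Trmt11 was called at low input, in all 4 libraries from 500 and 1000 cells. In the strongest class by fold of the autosomal consensus, with folds from 11.3, 32 of 8673 regions were in no low-input list. Peaks had been taken out of the low-input lists after calling. Absence of Bbs2, Hjurp, Cwc22 and Crebzf therefore does not measure loss at low input. Of the 181 genes missing at 20000 cells, 35 were called in all 6 low-input libraries. The strongest at 100 cells were Upk3b, a uroplakin gene (mean fold 10.96), Hsf2bp (10.8), Cc2d2b (9.17), Ctrl (8.38) and Ap1m2 (8.36). Each was called in all 6 low-input libraries except Ctrl, which was called in 4.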

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

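Of the tests here, the comparison of overlaps for depth, the count of other splits and the gap of the 20000-cell libraries on 1000-cell regions were chosen after the result was seen. The low-input lists lacked many of their own strongest peaks. Among the first 200 peak numbers, ranked by p, 43 and 44 were absent in the 100-cell replicates 1 and 2, 58 and 60 in the 500-cell replicates and 52 and 53 in the 1000-cell replicates, while the 20000-cell lists lacked none. This signal lies in the peak names, outside the measurements compared above. Of the first 200 peaks in each 20000-cell list, 16 overlapped no low-input list, of which 11 and 12 were autosomal.

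The 50000 strongest regions of the 20000-cell libraries overlapped each other at 88.5% and low-input lists at no more than 75.8%. Removal of regions by the authors does not account for it: without non-autosomal regions and regions that no low-input list overlapped, the pair stood 11.7 points above its highest overlap with a low-input list (89.0% against 77.2%). Noise from lower depth would make low-input lists overlap each other less than the 20000-cell lists. Among the 50000 strongest autosomal regions they overlapped each other 3.91 points more on average, in 6 of 6 libraries. In the whole lists this did not hold, so lower depth stays open. The mean autosomal Jaccard index there was 0.475 for low-input pairs and 0.479 for mixed pairs. Of 28 splits of 2 against 6 libraries, 1 gave a difference between within-class and between-class overlap as large (4.50 against 1.93 for the highest other). That count says nothing of chance, because it restates the high overlap of the pair. A preference of the low-input libraries for gene-dense sequence may contribute, since at matched fold and away from gene ends they recovered the gene-densest of 5 classes of 20000-cell regions 33.7 points more often than the gene-poorest (30.8 to 35.8), against 8.22 points between the 20000-cell libraries. Lower depth as the whole of that gap is argued against, since on 1000-cell regions the deeper 20000-cell libraries had a gap of −12.5 points on average (−12.6 and −12.5). A part from depth stays open, because the 100-cell libraries had a mean gap of 7.94 points there (10.2 and 5.69). This lay between the bounds set beforehand (over 20 for depth, under 10 in both against it). The 500-cell libraries, at more depth, had 8.04 and 7.36, and the 1000-cell replicates 1 and 2 on each other 4.87 and 6.86. Cell number, the input amount that the design varies, cannot be told apart from protocol at 20000 cells.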

How the results depend on the processing

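The lists of 50000 regions, and the autosome settings for gene ends, were chosen after seeing the data. Of 64 comparisons of a result with another setting, 57 kept their direction and their side of the threshold, or a count within 1.5 times. These leave out the percent of regions recovered at each low input, which moved by more than the preset margin in 18 of 21 other comparisons. With −log10 q of at least 5, the trend of region number became r = 0.937, that of gene-end share r = −0.915, genes missing at 100 cells numbered 993 and genes missing at 20000 cells 61; the cause was not tested. Gene-end share also passed the threshold in equal lists (r = −0.893) and in lists of 50000 regions (r = −0.941), but over the 6 low-input libraries alone the latter gave r = −0.785 (exact p = 0.0556). Unmerged peaks gave r = 0.704 for their number (exact p = 0.0516, n = 8). Genes missing at 100 cells numbered 152 on autosomes, because the low-input lists hold no other chromosome.

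Leaving out each library gave r from −0.0569 to 0.847 for region number, whose sign turned without 100-cell replicate 1 (−0.0213) or 20000-cell replicate 2 (−0.0569), and r from 0.221 to 0.843 for recovery. The range was −0.939 to −0.329 for gene-end share, 0.00659 to 0.0718 for the Jaccard excess, 611 to 862 for genes missing at 100 cells and 181 to 620 for genes missing at 20000 cells. Odds ratios of the granule lists were 7.12 to 9.27 at 100 cells, 8.69 to 11.2 at 500 cells and 7.61 to 10.0 at 1000 cells; at 20000 cells the lowest was 19.3, and without replicate 2, or with a region in at least 1 library, no granule gene lacked a region, so the ratio had no finite value. The gene-end excess in recovery was 15.4 to 20.7 points; with 5 libraries the smallest sign-flip p is 0.0625, so that test cannot pass there by construction.

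A replicate block gave r = 0.160 for region number, 0.531 for recovery and −0.553 for gene-end share and changed no call. Differences between replicates correlated across groups at −0.0298 to 0.00625, so the numbers do not pair the samples. The planned motif result and its alternatives were not run. With overlap of at least 50% of both regions, recovery was 39.9%, 40.6% and 45.3% at 100, 500 and 1000 cells. Among the 64, the stricter threshold changed 4 results, more than any other setting. The background was 0.865 reads in the shallowest library, so absence of a weak region there does not show closed chromatin.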

Other observations

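The list test in this paragraph and the comparison of pairs in the next were chosen after seeing the data, and the bounds used in the later paragraphs were set before their tests were run. Strong distal regions, those in the strongest of 10 classes of the autosomal consensus and over 1 kb from gene ends, numbered 4697, and 4590 of them were called in both 100-cell libraries. Among genes with these regions inside or within 20 kb, Lsamp, Nrxn3 and Tenm2, genes of neuronal adhesion and synapses, had 10 each, in spans of 2237, 1652 and 1270 kb. Gap43, a growth cone gene, had 5 within 132 kb. Of 23 autosomal genes of differentiating granule neurons 9 had at least 1, against 12.1% of all autosomal genes (odds ratio 4.67, Fisher's exact test, Benjamini-Hochberg p = 0.0140 over 15 lists), and all 14 of their regions were called in both 100-cell libraries. These genes had a median span of 136.5 kb against 57.5 kb for all genes, so length moves with the count. Per 100 kb the list had a mean of 0.305 such regions, beside 0.3095 for oligodendrocyte, 0.276 for cell cycle, 0.255 for Sonic hedgehog and 0.248 for Purkinje cell genes and 0.1435 for all genes, and these scaled values were not tested. Without the highest gene of each list these means were 0.147 (without Gap43), 0.165 (Mog), 0.171 (Pcna), 0.186 (Ccnd2) and 0.158 (Slc1a6), so each excess per length rested largely on 1 gene. Of 21 progenitor genes 1 had such a region, and no other list passed the test.

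The 20000-cell libraries shared 6574 autosomal consensus regions that no low-input library overlapped, and the highest number for any other pair of libraries was 1259. Their median number of genes within 500 kb was 2 and 62.7% lay outside genes, against 9 genes and 35.1% for regions called in all 8 libraries. These sets were not matched on fold or width, and their median widths were 302 and 1008 bp.

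In the opposite direction, 556 regions were called in all 6 low-input libraries and in neither 20000-cell library, with a median of 16 genes within 500 kb. Setting other pairs of libraries apart gave as many in 6 of 28 splits, the real one included (556, against 1101 for the highest other). The others with as many all set apart shallower libraries, from 100 or 500 cells. Splits that set apart 1 20000-cell and 1 low-input library gave 59 to 240. The count thus moves with the depth of the pair and cannot decide on chance, which stays open. Shifted edges of 20000-cell regions are argued against, since 17.1% lay within 1 kb of such a region, while too few reads at 20000 cells stays open, because the low-input reads scaled to that depth passed the calling threshold with a median chance of 100% only by selection, the regions having been picked as called in 6 shallower libraries. Epithelial cells in the low-input sorts, weighed with 16 marker genes because Upk3b was among the genes above, stay open too, although all libraries were sorted on Atoh1-GFP, a gate that should remove such cells. The count of 2 met the bound set against them, but only the 6 markers called in neither 20000-cell library could have counted, so the bound was wrong for this test: 14 were called in at least 1 low-input library and 8 in both 20000-cell libraries, and of the 6 that could count, 2 (Cldn4 and Ovol1) were in all 6 low-input libraries, Krt8 in 4, Krt5 in 2 and Krt18 and Krt14 in none; cell number stays open and untested for these regions.

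Lower depth alone was weighed for the loss of weak regions at low input. The prediction covered all autosomal regions of a 20000-cell library, so it does not speak of weak regions apart. The reads at each 20000-cell summit, scaled to the depth of a low-input library, predicted recovery of 65.5% ± 8.41, 83.1% ± 1.44 and 81.7% ± 0.0639 at 100, 500 and 1000 cells, against 57.9%, 57.7% and 63.1% observed (SD, n = 2 each). After taking off the shortfall of the 20000-cell libraries on each other, the remaining shortfall averaged −1.70 points and ran from −14.0 to 7.48 points across libraries, which met neither bound set beforehand, so depth and other differences cannot be told apart, because the correction need not be constant with depth. Of 15 pairs of low-input libraries, the deeper library recovered more in 9 and the shallower in 6, among them 100-cell replicate 2, which recovered 61.2% of autosomal regions at a background of 1.20 reads, against 55.7% at 2.21 in 500-cell replicate 2, a tally made after the values were seen. The tally did not equalise list length, and these 2 lists held 139288 and 115228 regions. Among the 50000 strongest regions of each library they recovered 72.5% and 71.9%. Cell number, which the design varies, stays open, since its trend with recovery did not pass the test (r = 0.530, exact p = 0.267, n = 6). The trend did not pass in lists of equal length either (r = 0.718, exact p = 0.122, n = 6). With the 50000 strongest regions it gave r = 0.825 (exact p = 0.0556, n = 6). Neither this trend nor the depth prediction was run on weak regions alone.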
